A study of Mus musculus with 24 samples.

How the data were processed

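Mature miRNAs were measured in liver and serum of male C57BL/6NJcl mice on 1-colour Agilent miRNA arrays labelled with Cy3. Per the labels, mice were bought at 5 weeks of age, acclimatized for 1 week, and then fed a choline-deficient, amino acid-defined high-fat diet with 0.1% methionine (the NASH model, for non-alcoholic steatohepatitis) or a standard chow (control). Liver and heart blood were taken after 1, 2 or 6 weeks of diet. Each tissue, diet and week had 2 arrays, so that 12 groups held 24 arrays. The labels do not say whether the arrays of a group came from separate mice or pools, so p-values measure the spread between these arrays, which may be partly technical. Per the labels' protocols, 100 ng of liver RNA or 2.5 ng of serum RNA was labelled, the latter extracted from 200 uL of serum.

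The deposited files hold scanner intensity per spot, per the file headers, as extracted by Agilent Feature Extraction (version 11.5 per the submitters' processing notes). The processed signal in them is the background-subtracted intensity, and no normalization between arrays had been applied. The files also carry a total signal and a detection flag per miRNA. The arrays hold probes for 1881 mouse miRNAs, and miRNA names are those of the files.

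Control spots and spots with outlier flags were left out, and the spots of a probe were averaged. Each array was divided by the 75th percentile of its signal over the probes well above background on all 12 arrays of the tissue (299 probes in liver, 253 in serum). A single floor per tissue was then set and log2 was taken. The floor was the median over arrays of the 5th percentile of scaled signals well above background. A miRNA was represented by its brightest probe, and 388 miRNAs in liver and 426 in serum, detected on at least 2 arrays of the tissue, were tested. Of these values 35.6% in liver and 39.1% in serum lay at the floor. Among the miRNAs called for diet, 23 of 164 in liver and 6 of 80 in serum had another probe that went the opposite way.

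Within each tissue limma (version 3.58.1, R 4.3.3) was fitted to the 6 diet-by-week groups with eBayes, and contrasts were the mean of the 3 weekly NASH minus control differences, each week alone, the difference between weeks in the diet effect, and control week 6 minus week 1. Benjamini-Hochberg adjusted p below 0.05 counted as a call. The diet effect in serum minus that in liver was tested in 1 limma fit over all 24 arrays for the 293 miRNAs tested in both. The 15 miRNA lists were tested with camera at a preset correlation of 0.01 where at least 3 members were tested. Array quality and a serum haemolysis index (log2 miR-451a minus log2 miR-23a-3p) were compared by two-sided exact permutation of diet within weeks, whose smallest possible p is 0.00926. The lists were hepatocyte-enriched, immune cells, stellate cell and fibrosis, miR-29 family, p53-linked miR-34 family, miR-17-92 and paralogous clusters, lipid metabolism, let-7 family, miR-200 family, Dlk1-Dio3 imprinted cluster, endothelium, red cells, platelets, skeletal and heart muscle, and pancreas and neuroendocrine cells.

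The groups, tests, lists, main alternatives and naming rule were set before the data were examined. The rule named the 10 most changed miRNAs per direction with adjusted p below the threshold and the same sign in all 3 weeks, up to 5 per direction in each week, up to 5 for the week and age contrasts, up to 4 members per list, and 6 fixed miRNAs. Where no array of a diet (for a single week, of a group) detected a miRNA, its fold is given only as a bound. Means over weeks of miRNAs that only some arrays of a diet detected rest in part on the floor and can be understated. Arrays at the floor show no spread, so the SE and p-values of such miRNAs can be too small as well. The eBayes prior had 0.49 degrees of freedom in liver and 0.53 in serum, against 6 residual ones, and so corrects this little. Alternatives changed the signal column, background correction, scaling, probe summary, floor, filter, variance model and blocks, and left out each array in turn. The normexp alternative was run on the median spot signal and the median local background, and quantile normalization on the normexp signal, so that it changes background correction as well as scaling.

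The arrays lay on 3 slides of 8. Serum weeks 1 and 2 shared the first slide, serum week 6 and liver week 1 the second, and liver weeks 2 and 6 the third. Both diets of each week were on 1 slide, so weekly diet contrasts are within-slide values and a slide block leaves them as they are. Control week 6 and week 1 were on different slides in both tissues, and slide and week cannot be told apart there. Replicate number coincided with the row on the slide. Control arrays lay in columns 1 and 3 and NASH arrays in columns 2 and 4 of every slide, so that diet and slide column cannot be told apart. The deviations of same-numbered NASH and control arrays from their group means correlated at 0.53, 0.13 and 0.18 in serum at weeks 1, 2 and 6, where 1 array of week 6 has no number, and at -0.46, 0.33 and 0.44 in liver. With all above 0.1, the numbers were taken to pair the serum arrays, after the blocked counts had been seen, while in liver they were not. This rests on the check and the shared row and not on a shared origin in the labels. The 2 arrays of a group deviate by equal and opposite amounts, so each week gives only 1 correlation. The check is thus weak, and the pairing of the serum arrays stays uncertain. Unless a block is named, serum values below are from the fit without a block. Blocked values are given with replicate number, which leaves out the serum array without a number, and with slide row, which keeps all 12 arrays. No replicate arrays of a group shared a probe value, and their log2 signals correlated across miRNAs at 0.981 to 0.997 in liver and 0.951 to 0.980 in serum.

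The fit was tested on simulated data made from the arrays' own means, spreads and scaling factors, in 20 runs of 60 changed miRNAs. For the mean over weeks, 69.3% of liver and 34.0% of serum changes of 1 log2 unit were called, and 82.3% and 68.0% of changes of 2 units, none with the wrong sign. In liver 21% of calls were false, against 5.37% with the true array factors, because changed miRNAs moved the percentile itself, by up to 0.36 log2 units. In serum the shares were 8.79% and 7.09%. The simulated changes had random sign and independent noise, and moved the serum percentile by up to 0.24 log2 units. On the real serum arrays the median difference of miRNAs detected on all arrays was -0.28 as scaled and 0.35 over all probes. These shares therefore need not describe the real calls. The number of arrays limits the precision.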

Results

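Mature miRNAs were profiled in liver and serum of mice fed a choline-deficient high-fat diet, which produces steatohepatitis (NASH), and of mice fed chow. The arrays covered 1, 2 and 6 weeks of feeding, with 2 arrays for each tissue, diet and week, so that each tissue had 6 NASH and 6 control arrays. Between 253 and 379 miRNAs were detected on a liver array and between 235 and 399 on a serum array. The comparisons ask which miRNAs differ with the diet in each tissue, whether the difference changes between weeks, and whether liver and serum differ in it. Values are log2 differences, NASH minus control, with the standard error (SE) of the limma fit and adjusted p over all miRNAs tested in the tissue; the mean over weeks rests on 6 against 6 arrays and a single week on 2 against 2.

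NASH arrays detected more miRNAs than control arrays in both tissues. In liver the number was 354.5 ± 18.6 (SD, n = 6) against 288.8 ± 22.8 (SD, n = 6), and the exact permutation p was 0.00926, the smallest this design allows. In serum it was 347.7 ± 37.9 against 295.8 ± 49.9, with the same exact permutation p for n = 6 against 6. The percentile used for scaling was also higher on NASH arrays, by 0.43 log2 units in liver (exact permutation p = 0.0185) and by 0.78 in serum (exact permutation p = 0.0278), so that the levels below are relative to the brighter miRNAs of the same array. Signals of the spike-in controls ranged over serum arrays by 0.32 to 1.90 log2 units, depending on the control, and over liver arrays by 0.39 to 0.59. They were not compared between diets. Each slide column held arrays of 1 diet, so diet and slide column cannot be told apart.

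In liver, miR-34a-5p, a direct transcriptional target of p53, rose 7.23-fold over the 3 weeks (log2 difference 2.85, SE 0.11, adjusted p = 6.04e-06) and was higher in 6 of 6 NASH arrays than the control mean of its week. It was 3.91-fold higher at week 1, 8.12-fold at week 2 and 11.9-fold at week 6. miR-342-3p, which is abundant in lymphocytes, rose 5.30-fold (2.41, SE 0.10, adjusted p = 6.08e-06), and the myeloid miR-223-3p rose 3.33-fold (1.73, SE 0.19, adjusted p = 4.52e-04). miR-214-3p, which shares a primary transcript with miR-199a and is found in activated stellate cells and fibroblasts, rose 2.96-fold (1.57, SE 0.08, adjusted p = 2.04e-05). miR-122-5p, the most abundant hepatocyte miRNA, fell to 0.507 of control (-0.98, SE 0.05, adjusted p = 2.87e-05) and was lower in 6 of 6 NASH arrays.

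**Figure D1:**
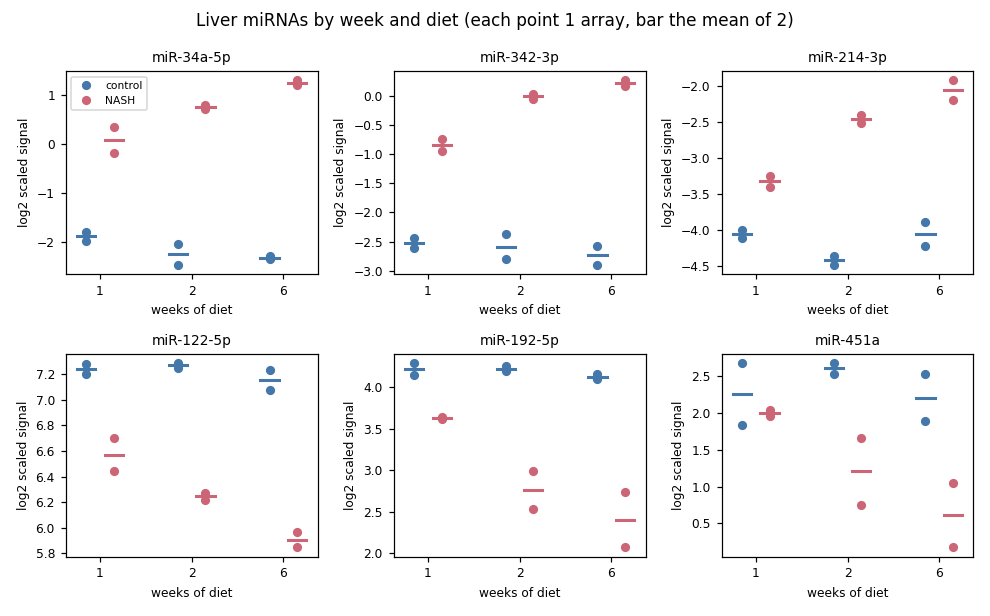
Log2 scaled signal (vertical axis) of 6 miRNAs in liver against weeks of diet (horizontal axis), with 1 point per array and a bar at the mean of 2 arrays. miR-34a-5p, miR-342-3p and miR-214-3p were higher on NASH arrays in each week, by 1.97, 1.69 and 0.73 at week 1 and by 3.58, 2.95 and 1.99 at week 6, while miR-122-5p and miR-192-5p were lower; miR-451a was lower by a weekly difference of -0.26, -1.40 and -1.60.

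Other liver miRNAs that rose in the mean over weeks were miR-7118-5p (2.31), miR-5128 (2.05), miR-3102-5p (1.91), miR-2861 (1.78), miR-8110 (1.39) and miR-1949 (1.36), all higher in 6 of 6 arrays; miR-2861 was detected on 4 of 6 control arrays. The liver miRNAs that fell furthest were miR-144-3p (-1.55, SE 0.39, adjusted p = 0.019), miR-122-3p (-1.51, SE 0.15), miR-101c (-1.48), miR-101b-3p (-1.28), miR-101a-3p (-1.26), miR-192-5p (-1.26), miR-203-3p (-1.12), miR-192-3p (-1.12), miR-451a (-1.09) and miR-19b-3p (-1.07). miR-21a-5p, often raised in fibrotic tissue, did not pass in liver (-0.58, SE 0.27, adjusted p = 0.14), and its sign turned under another scaling. miR-23a-3p rose by 0.50 (SE 0.09, adjusted p = 0.004). With slide row as a block 59 of 64 named liver calls passed; miR-19b-3p, miR-211-3p, miR-29c-5p, miR-93-5p and miR-20a-5p did not.

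Hepatocyte-enriched miRNAs fell as a group in liver. Of 10 tested members, 9 fell, 0 rose and 1 did not pass, and 9 fell when adjusted over the list alone. They included miR-194-5p (-1.06, SE 0.06), which is made with miR-192, miR-455-3p (-1.04, SE 0.08), miR-193a-3p (-0.85, SE 0.03) and miR-148a-3p (-0.68, SE 0.12), while miR-802-5p was at 0.35 (SE 0.30, adjusted p = 0.445). camera gave an adjusted p of 8.17e-06 for the list, and the adjusted p was 0.381 with an estimated correlation. Lipid metabolism miRNAs counted 6 that fell, 1 that rose and 3 that did not pass, with the same counts adjusted over the list alone. Of the 6, 2 kept their sign under the 4 other scalings. miR-103-3p, miR-107-3p, miR-27b-3p and miR-378a-5p were above 0 without scaling (0.14, 0.054, 0.011 and 0.12). miR-30c-5p fell by 0.85 (SE 0.06) and miR-33-5p, encoded within Srebf2, fell by 0.75 (SE 0.09), whereas miR-27a-3p rose by 1.04 (SE 0.13); camera's adjusted p was 0.0395, and the adjusted p was 0.428 with an estimated correlation.

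Of 11 immune cell miRNAs tested in liver, 6 rose, 2 fell and 3 did not pass, and 8 rose and 2 fell when adjusted over the list alone. Beside miR-342-3p and miR-223-3p, miR-155-5p, which is induced in activated immune cells, rose by 1.28 (SE 0.10) and miR-132-3p by 0.95 (SE 0.05), each detected on 1 of 6 control arrays, while miR-212-3p fell by 0.73 (SE 0.02). The list had a camera adjusted p of 0.0395, and an adjusted p of 0.496 with an estimated correlation. Of 12 stellate cell and fibrosis miRNAs, 5 rose, 0 fell and 7 did not pass, as also when adjusted over the list alone; miR-199b-5p rose by 1.23 (SE 0.21), miR-199a-5p by 0.87 (SE 0.12) and miR-221-3p by 0.71 (SE 0.06). camera's adjusted p was 0.0395 for this list, and the adjusted p was 0.428 with an estimated correlation. Of 14 miRNAs of the Dlk1-Dio3 imprinted cluster, 5 rose and 9 did not pass, as also when adjusted over the list alone, with miR-379-5p at 1.33 (SE 0.18) and miR-127-3p at 0.99 (SE 0.13), each detected on 1 of 6 control arrays. Its camera adjusted p was 0.0395 and its adjusted p was 0.546 with an estimated correlation.

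Red cell miRNAs were lower in the same liver arrays. Of 5 tested, 3 fell (miR-144-3p, miR-451a and miR-144-5p, the last with a difference of -0.84, SE 0.12) and 2 did not pass, as also when adjusted over the list alone, with a camera adjusted p of 0.0397 and an adjusted p of 0.496 with an estimated correlation. The endothelial miR-126a-3p fell by 0.53 (SE 0.13) and miR-126a-5p by 0.94 (SE 0.29), the former with a value of 0.032 under quantile normalization. Of 9 let-7 family members 7 fell and 2 rose, as also when adjusted over the list alone. Of the 7 that fell, 1 kept its sign under the 4 other scalings, let-7g-5p (-0.85, SE 0.10). let-7a-5p (-0.23) turned to 0.20 without scaling and to 0.48 under quantile normalization, let-7f-5p (-0.63) to 0.065 under quantile normalization and miR-98-5p (-0.37) to 0.058 without scaling. let-7b-5p (-0.26), let-7c-5p (-0.21) and let-7d-5p (-0.14) turned under both. The let-7 list had a camera adjusted p of 0.0429 and an adjusted p of 0.428 with an estimated correlation. The miR-29 family (0 rose, 1 fell, 3 did not pass), the miR-17-92 clusters (2 rose, 2 fell, 6 did not pass; 3 rose and 4 fell adjusted over the list alone), the miR-200 family (0 of 5 passed) and platelet miRNAs (2 rose, 1 fell, 1 did not pass) had camera adjusted p of 0.134, 0.744, 0.308 and 0.656. The fall of miR-29c-5p in the miR-29 family, of miR-20a-5p in the miR-17-92 clusters and of miR-126a-3p among platelet miRNAs did not keep its sign under the other scalings. Of the miR-34 family, miR-34b-5p was detected on 4 NASH arrays and 0 control arrays, at the floor in both.

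In liver 164 of 388 miRNAs passed in the mean over weeks, 85 higher and 79 lower. The split was 64 higher and 38 lower when scaled over all probes, 115 and 130 under quantile normalization, 79 and 90 under median centring, and 117 and 9 without scaling; under normexp background correction it was 32 and 172. The median difference of miRNAs detected on all arrays was -0.06 as scaled, -0.13 under median centring and 0.30 without scaling; 138 of the 164 kept their sign under all 4 other scalings, 84 of them higher and 54 lower. On simulated liver arrays 21% of calls were false, and a test against a change of at least 0.5 log2 units, chosen after the data were seen, left 49 miRNAs, 27 higher and 22 lower.

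By week, 45 liver miRNAs passed at week 1 (24 higher, 21 lower), 119 at week 2 (71 and 48) and 110 at week 6 (48 and 62). At week 1 miR-467b-3p (3.09) and miR-744-3p (2.09) were among the most increased, and miR-5100 (-0.94), miR-6412 (-0.91), miR-455-3p (-0.84), miR-193a-5p (-0.83) and miR-22-3p (-0.79) among the most decreased. miR-467b-3p was also lower in control arrays of week 1 than in those of week 6, so its week 1 difference need not come from the diet. At week 2 miR-7118-5p (3.76), miR-211-3p (2.85) and miR-31-3p (-1.34) stood out, and at week 6 miR-379-5p (2.37). Within the hepatocyte-enriched list 5 of 10 fell at week 1, 9 at week 2 and 9 at week 6. Of the 14 Dlk1-Dio3 members 0 rose at week 1, 2 at week 2 and 6 at week 6. Camera gave that list an adjusted p of 0.733, 0.567 and 6.90e-04, the last 0.405 with an estimated correlation. A difference between weeks was not tested for lists. The test of a difference between weeks passed for 13 miRNAs, and for 6 to 37 when single arrays were left out. Among these, miR-193a-3p (-0.42, -0.90 and -1.23 at weeks 1, 2 and 6) and miR-3968 (-0.70, -1.18 and -1.17) were detected on all arrays, but in the fit of such miRNAs alone 0 of 218 passed in limma (44 at an unadjusted p under 0.05). By contrast miR-342-5p, detected on 0 control arrays, miR-7241-5p and miR-574-3p lay at the floor in part of the groups. Leaving out an array of week 1 moved the week 1 count to 13 and 21 (control replicates 1 and 2) and to 18 and 26 (NASH replicates 1 and 2), and with slide row as a block it was 12 and the difference between weeks passed for 1. Scaled over all probes the splits of weeks 1, 2 and 6 were 9 higher and 0 lower, 25 and 26, and 28 and 4; without scaling they were 14 and 0, 64 and 2, and 41 and 0. Under normexp they were 3 and 4, 15 and 35, and 13 and 54. The split of week 2 was 46 and 75 under median centring and 82 and 97 under quantile normalization. Without control week 2 replicate 1 it was 47 and 55, and that of week 6 was 55 and 42 without NASH week 6 replicate 1.

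In control liver, 2 miRNAs differed between week 6 and week 1, miR-467b-3p (2.98, adjusted p = 0.0498) and miR-185-5p (-0.43, adjusted p = 0.00659). Leaving out single arrays gave between 1 and 5, and slide row as a block 0 in limma (31 at an unadjusted p under 0.05). Under normexp and median centring it was also 0 (3 and 21 unadjusted), and over all probes and without scaling both calls were higher. These weeks were on different slides, and slide and week cannot be told apart.

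In serum, miR-122-5p rose 14.1-fold with the NASH diet (log2 difference 3.82, SE 0.57, adjusted p = 0.006) and was higher in 6 of 6 NASH arrays than the control mean of its week. miR-192-5p rose 6.30-fold (2.65, SE 0.22, adjusted p = 0.00107), miR-34a-5p rose 4.01-fold (2.00, SE 0.14, adjusted p = 0.00107) and miR-342-3p rose 3.25-fold (1.70, SE 0.26, adjusted p = 0.006). miR-122-3p was detected on 6 NASH arrays and 0 control arrays and was at least 2.35-fold higher (adjusted p = 0.00107). miR-205-5p, an epithelial miRNA, fell to 0.130 of control (-2.94, SE 0.28, adjusted p = 0.00154), and the islet and neuroendocrine miR-375-3p fell to 0.182 of control (-2.46, SE 0.26, adjusted p = 0.00217). Both were lower in 6 of 6 NASH arrays.

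**Figure D2:**
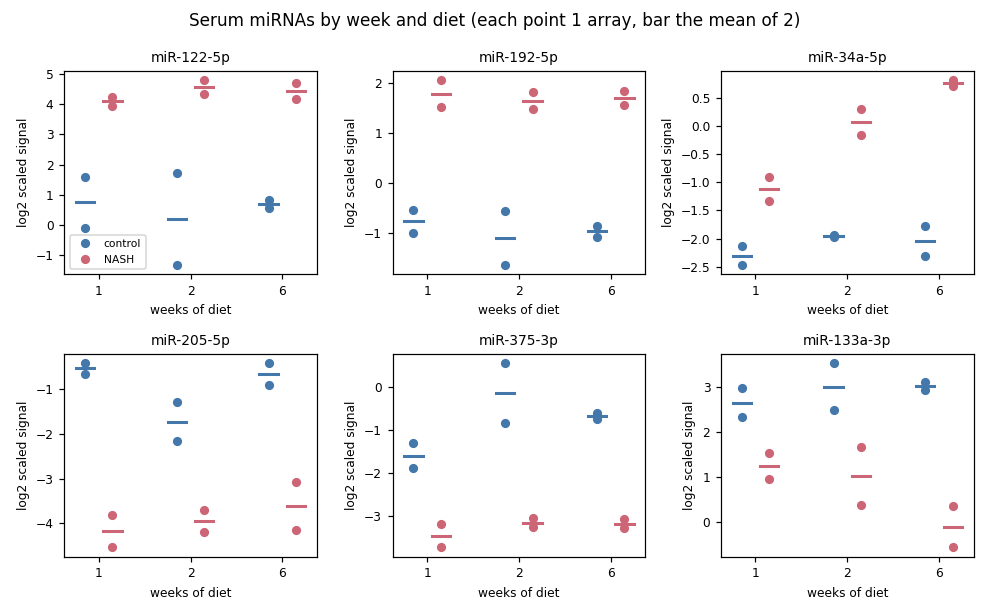
Log2 scaled signal (vertical axis) of 6 miRNAs in serum against weeks of diet (horizontal axis), with 1 point per array and a bar at the mean of 2 arrays. miR-122-5p, miR-192-5p and miR-34a-5p were higher on NASH arrays in each week, by 3.35, 2.55 and 1.18 at week 1 and by 3.75, 2.68 and 2.80 at week 6, and miR-205-5p, miR-375-3p and miR-133a-3p were lower, by a difference of -3.64, -1.86 and -1.41 at week 1.

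With the replicate block, which leaves out a serum array, miR-122-5p, miR-192-5p, miR-342-3p, miR-205-5p and miR-375-3p were among 29 of 42 named serum calls that did not pass. With slide row as a block on all arrays these 5 passed and 4 of the 42 did not (miR-133a-3p, miR-344i, miR-378a-5p and miR-200b-3p). Other serum miRNAs that rose were miR-6931-5p (1.86), miR-148a-3p (1.64), miR-7040-5p (1.60), miR-8109 (1.41) and miR-21a-5p (1.33, SE 0.29, adjusted p = 0.0226); of control arrays 3 of 6 detected miR-7040-5p and 2 of 6 miR-8109. Those that fell included miR-214-3p (-2.05, SE 0.21), miR-193b-3p (-1.88), miR-497a-5p (-1.60), miR-486a-5p (-1.56), miR-128-3p (-1.55) and miR-3968 (-1.42). The muscle miRNAs miR-133a-3p and miR-133b-3p, which differ little in sequence and may share signal on the array, both fell by 2.18 (SE 0.34 and 0.33). Each of these that fell was lower in 6 of 6 arrays.

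Hepatocyte-enriched miRNAs rose as a group in serum, where the haemolysis index (log2 miR-451a minus miR-23a-3p) differed by -0.44 in the mean over weeks. Of 9 tested members 5 rose, 0 fell and 4 did not pass, and 7 rose when adjusted over the list alone, with miR-193a-3p, detected on 1 of 6 control arrays, at 0.52 (SE 0.09) and miR-194-5p at 0.82 (SE 0.24, adjusted p = 0.0585). camera's adjusted p was 2.89e-08, and the adjusted p was 0.261 with an estimated correlation. No other list passed camera in the mean over weeks, except that with slide row as a block red cell miRNAs (adjusted p = 0.0497) and the miR-17-92 clusters (adjusted p = 0.0445) passed as lower. Red cell miRNAs also passed with the replicate block (adjusted p = 0.0346). With an estimated correlation, run only without a block, camera gave the red cell and miR-17-92 lists an adjusted p of 0.827 each. Red cell miRNAs (2 of 4 fell) had an adjusted p of 0.18, skeletal and heart muscle (2 of 5 fell) 0.18, the miR-17-92 clusters (3 of 10 fell, 2 of which kept their sign under the 4 other scalings) 0.18 and the miR-200 family (2 of 5 fell, 3 adjusted over the list alone) 0.18. The miR-29 family (0 of 4 passed) had 0.432 and platelets (1 of 4 fell) 0.432. Stellate cell and fibrosis miRNAs (2 rose and 3 fell of 11; 6 fell adjusted over the list alone) had 0.465, immune cells (2 rose and 4 fell of 12; 2 of the 4 kept their sign under the other scalings) 0.743, the Dlk1-Dio3 cluster (0 of 8 passed) 0.743, lipid metabolism (1 of 8 fell, 2 adjusted over the list alone) 0.829 and let-7 (0 of 7 passed) 0.92. The immune list had a median of -0.10 and a mean of -0.05 while camera's direction was up, and the Dlk1-Dio3 list a median of -0.07 and a mean of -0.04 with direction up. In the fit with the replicate block the hepatocyte-enriched list, still higher in camera (adjusted p = 1.84e-06), had 2 of 9 members that rose, miR-122-3p and miR-365-3p. Of the immune list 1 fell (miR-155-5p), as did 1 of the stellate list (miR-214-3p), 1 of the miR-17-92 clusters (miR-106b-5p) and 1 of the red cell list (miR-486a-5p). The members that passed without a block of the lipid, miR-200, muscle and pancreas lists did not pass with this block, while 2 of the Dlk1-Dio3 cluster rose. With slide row as a block the same 5 hepatocyte-enriched members rose (camera adjusted p = 1.23e-06), 2 immune members rose and 3 fell, 2 stellate members rose and 5 fell, 4 of 4 red cell members fell, and 1 member of the miR-200 list and 1 of the muscle list fell. let-7b-5p also fell with slide row, and miR-103-3p took the place of miR-378a-5p as the lipid member that fell. Of the platelet list miR-126a-3p and miR-151-5p fell with either block. Of the lists too short for camera, endothelial miR-126a-3p (-0.997, SE 0.42, adjusted p = 0.182) did not pass, nor did miR-126a-5p (-0.05, adjusted p = 0.703), though miR-126a-3p passed as lower with either block, miR-34a-5p was the tested member of the miR-34 family, and miR-375-3p was the tested member of the pancreas list.

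In serum 80 of 426 miRNAs passed in the mean over weeks, 21 higher and 59 lower. The split turned to 32 higher and 7 lower when scaled over all probes, 37 and 7 without scaling and 44 and 21 under median centring, and was 53 and 45 under quantile normalization. The median difference of miRNAs detected on all arrays was -0.28 as scaled, 0.35 over all probes, 0.44 without scaling, 0.23 under median centring and -0.01 under quantile normalization. All 21 higher calls and 49 of the 59 lower calls kept their sign under these 4 scalings. A test against a change of at least 0.5, chosen after the data were seen, left 23, of which 9 were higher and 14 lower. Without NASH week 1 replicate 1, NASH week 2 replicate 1 or NASH week 6 replicate 2 the count was 51, 49 and 51. With the replicate block it was 30 (11 higher, 19 lower), against 69 when the array without a number (NASH week 6) was left out with no block, and with slide row as a block on all 12 arrays it was 76 (18 higher, 58 lower). Under normexp it was 362, of which 16 were higher.

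By week, 6 serum miRNAs passed at week 1 (2 higher, 4 lower), 11 at week 2 (5 and 6) and 51 at week 6 (23 and 28). At week 1 miR-192-5p and miR-122-3p were higher and miR-205-5p, miR-712-5p (-0.996), miR-344i (-0.76) and miR-721 (-0.59) lower. miR-344i and miR-721 were also higher in control arrays of week 1 than in those of week 6, so their week 1 differences need not come from the diet. Control week 1 replicate 2 had 6.01% flagged spots, the most of any serum array. At week 2 miR-5119, miR-181b-5p (-1.77) and miR-181a-5p (-1.63) were lower, and at week 6 miR-26a-5p (-2.59). The haemolysis index of NASH minus control was 0.70 at week 1, 0.52 at week 2 and -2.54 at week 6; over the 6 against 6 arrays it did not differ in a two-sided exact permutation test (p = 0.417). At week 6 red cell miRNAs were lower as a list (camera adjusted p = 0.0373, and an adjusted p of 0.559 with an estimated correlation), with 1 of 4 members passing and 3 adjusted over the list alone. The let-7 list had a mean of 0.21 at week 1, 0.46 at week 2 and -1.55 at week 6, which offset each other in the mean over weeks. In each week 0 of 7 let-7 members passed, and the camera adjusted p was 0.335, 0.0902 and 0.0657. With the index as a covariate 0 miRNAs passed at week 6 in limma, with 17 at an unadjusted p under 0.05, and 39 passed in the mean over weeks. At week 6 the index parted the diets by far more than it varied within them (SD 0.19 in control, 0.10 in NASH arrays). The covariate could remove week 6 calls for that reason alone, so this fit does not tell red cell RNA from diet there. The mean of weeks 1 and 2 alone, chosen after the data were seen, gave 36, of which 12 were higher and 24 lower. Slide row as a block gave 0 at week 1 and 0 at week 2 in limma (60 and 83 at an unadjusted p under 0.05) and 58 at week 6 (14 higher, 44 lower). The replicate block gave 0, 0 and 16 in limma (47, 79 and 92 at an unadjusted p under 0.05), where leaving out the array without a number alone gave 6, 14 and 37. Scaled over all probes the splits of weeks 1, 2 and 6 were 7 higher and 4 lower, 17 and 1, and 19 and 2; without scaling they were 7 and 6, 11 and 1, and 29 and 1. Under median centring they were 4 and 1, 10 and 3, and 37 and 19, and under normexp 5 and 10, 10 and 320, and 18 and 317. Leaving out single arrays moved the week 1 count between 1 and 14. The week 2 count was 0 without either NASH array of week 2 (45 and 50 at an unadjusted p under 0.05 in limma) and 53 without control week 2 replicate 1, and the week 6 count was 12 without NASH week 6 replicate 2 and 19 without control week 6 replicate 1.

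**Figure D3:**
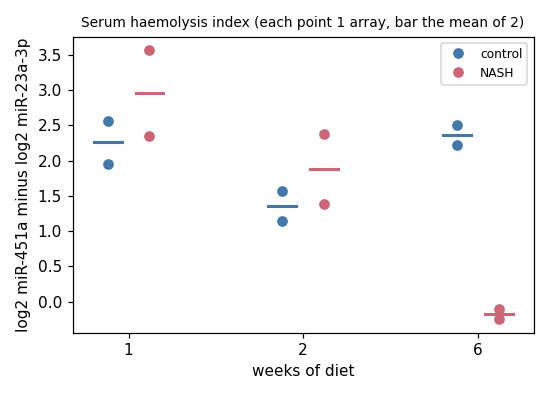
Haemolysis index (log2 miR-451a minus log2 miR-23a-3p, vertical axis) of each serum array against weeks of diet (horizontal axis), with a bar at the mean of 2 arrays. Both NASH arrays of week 6 lay at -0.11 and -0.25, below the other serum arrays.

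The test of a difference between weeks passed for 2 serum miRNAs, miR-721 (adjusted p = 0.0467) and miR-155-5p (adjusted p = 0.00141), both at the floor in part of the groups; without single arrays the count lay between 1 and 32, and with the replicate block it was 0 in limma (44 at an unadjusted p under 0.05). It was also 0 under normexp, under quantile normalization, without scaling and over miRNAs detected on all arrays (54, 51, 44 and 30 unadjusted). In control serum 8 miRNAs differed between week 6 and week 1, 4 higher and 4 lower, among them miR-155-5p (0.58), miR-1249-3p (0.66), miR-200c-3p (0.82), miR-344i and miR-721, the last 2 lower and detected on 0 control arrays of week 6. The count with the replicate block was 3. It was 77 (0 higher, 77 lower) without scaling, 313 (301 higher, 12 lower) under normexp, 2 (0 and 2) over all probes and 0 under quantile normalization in limma (94 at an unadjusted p under 0.05). The count lay between 4 and 30 without single arrays. Week and slide cannot be told apart there.

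Liver and serum were compared for 293 miRNAs tested in both. miR-122-5p was lower in liver and higher in serum, and the serum minus liver difference of the diet effect was 4.80; it was 3.91 for miR-192-5p and 2.32 for miR-148a-3p, and at least 2.75 for miR-122-3p, which no serum control array detected. miR-214-3p went the other way, higher in liver and lower in serum (-3.61), as did miR-199b-5p (-2.50), miR-181a-5p (-2.29) and miR-199a-5p (-2.16), the last 2 detected on 3 and 4 of 6 serum NASH arrays. miR-34a-5p and miR-342-3p rose in both tissues.

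**Figure D4:**
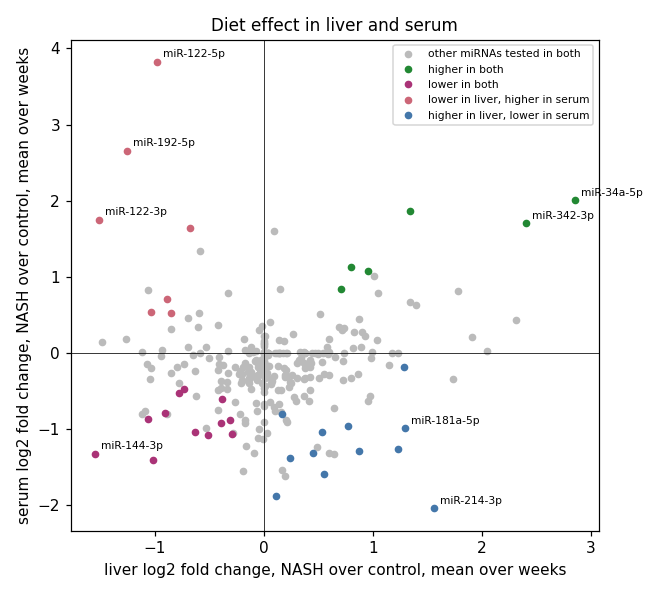
Log2 difference of NASH and control, mean over weeks, in serum (vertical axis) against liver (horizontal axis) for the 293 miRNAs tested in both, with 1 point per miRNA. Coloured points are miRNAs called in both tissues, of which 6 were higher in both, 12 lower in both, 7 lower in liver and higher in serum, and 12 higher in liver and lower in serum.

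The diet effect differed between the tissues for 102 of the 293, of which 24 were higher and 78 lower in serum than in liver by the joint limma fit. Scaled over all probes the count was 67, with 40 higher and 27 lower, and without scaling 64, with 25 and 39; under quantile normalization it was 44 and 51 and under median centring 59 and 40. Across miRNAs, which are not independent replicates, the effects had a Pearson r of 0.076 and a Spearman rho of 0.117. Of miRNAs called in both tissues, 6 were higher in both (4.10 for independent lists; Fisher's exact p = 0.253), 12 lower in both (9.61; p = 0.33), 7 lower in liver and higher in serum (3.49; p = 0.0544) and 12 higher in liver and lower in serum (11.3; p = 0.852), so none of these Fisher's exact tests passed. Of the 12 lower in both, 5 kept their sign in both tissues under the 4 other scalings, against 6 of 6, 7 of 7 and 11 of 12 in the other classes. The 4 counts with the replicate block were 3, 5, 3 and 4, and with slide row as a block 6, 15, 6 and 13.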

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

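The tests on scaling, hepatocyte share, red cell RNA and array brightness were chosen after the results they bear on were seen, those on serum scaling and on brightness in place of earlier ones whose outcome the design fixed, and the way splits were drawn for the tissue difference was revised after a first run; the split tests of each tissue were chosen beforehand.

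The difference between liver and serum in the diet effect passed for 102 miRNAs, and for between 59 (miRNAs detected on all arrays) and 132 (with the replicate block) in the alternatives. The serum minus liver difference was 4.80 for miR-122-5p, 3.91 for miR-192-5p, 2.32 for miR-148a-3p, 1.60 for miR-22-3p and 1.37 for miR-193a-3p. For miR-122-3p, which no serum control array detected, it was at least 2.75, the bound in serum minus the liver value. It was -3.61 for miR-214-3p, -2.50 for miR-199b-5p, -2.29 for miR-181a-5p, -2.16 for miR-199a-5p, -2.15 for miR-497a-5p, -1.997 for miR-193b-3p, -1.48 for miR-155-5p and -0.98 for miR-93-5p. Of the 6 NASH serum arrays, 3 detected miR-181a-5p, 4 miR-199a-5p and 2 miR-155-5p.

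The diet effect differed between weeks for 13 miRNAs in liver and 2 in serum. The count was 1 in liver with slide row as a block, and 0 in serum with the replicate block in limma (44 at an unadjusted p under 0.05). It was 0 in both tissues under normexp (18 and 54 unadjusted) and over miRNAs detected on all arrays (44 and 30 unadjusted), and without single arrays 6 to 37 in liver and 1 to 32 in serum. The highest minus the lowest weekly effect in liver, a measure chosen after the data were seen, was 0.48 for miR-3968 and 0.81 for miR-193a-3p. The other named miRNAs lay at the floor on some arrays, so that only the adjusted p of the limma test is given. It was 1.04e-04 for miR-342-5p, 0.00845 for miR-7241-5p and 0.00845 for miR-574-3p in liver, and 0.0467 for miR-721 and 0.00141 for miR-155-5p in serum.

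Hepatocyte-enriched miRNAs were lower in liver and higher in serum with the NASH diet, where 5 of 9 serum members passed, and 2 of 9 with the replicate block (camera adjusted p = 1.84e-06 for the list). With an estimated correlation and no block, the camera adjusted p of the list was 0.261 in serum and 0.381 in liver. Against the choice of scaling as the cause in serum, the list mean was 1.02 higher under quantile normalization (exact permutation p = 0.00926). There the median of miRNAs detected on all arrays was -0.01, which also lies above that as scaled (-0.28). Quantile normalization changed background correction too, so it does not test scaling alone. As scaled, where NASH values were lowest by that median, the list mean was 1.26 higher (exact permutation p = 0.00926). The list mean was 1.65 higher when scaled over all probes and 1.57 under median centring (exact permutation p = 0.00926 for each). These 2 cannot decide it, since they raise NASH values (medians of 0.35 and 0.23, against -0.28 as scaled) and could only raise the list. In liver the list mean was -0.88 over all probes, -0.96 under median centring and -0.52 under quantile normalization (exact permutation p = 0.0185, 0.00926 and 0.00926). Without scaling it was -0.47 (exact permutation p = 0.0926). The 9 members called lower in liver all kept their sign under these 4. The unscaled fall did not pass, so that scaling stays open as a cause, in whole or in part, of the fall in liver. A lower share of hepatocytes alone would raise other cell types alike. Immune cell miRNAs instead rose against red cell and endothelial ones by 1.48 (exact permutation p = 0.00926). That these lists parted was already seen when the comparison was chosen. A lower share together with another change could give the same value, so the comparison cannot exclude a lower share. A change in the immune cells themselves and release of hepatocyte miRNAs into serum remain untested hypotheses that may apply.

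More serum miRNAs were lower than higher, 59 against 21. Under 3 other scalings no more were lower than higher (45 and 53 under quantile normalization, 21 and 44 under median centring, 7 and 32 over all probes), so that the excess of lower calls may come from the scaling. The 28 miRNAs lower at week 6 had a median of -0.97 (SE 0.15) in weeks 1 and 2, where the haemolysis index was not lower. Its reference miR-23a-3p was lower on NASH arrays of week 1, at 2.41 and 2.56 against 2.97 and 3.41 in control. The index could thus rise without more red cell RNA. The red cell list had a mean of -0.50 at week 1 and -0.64 at week 2 (camera adjusted p = 0.329 and 0.669). These values therefore cannot decide whether less red cell RNA in week 6 NASH serum was the whole cause. All miRNAs detected on every serum array had a median of -0.49 in weeks 1 and 2. The 28 had a median of -0.32 there without scaling, so part of the -0.97 goes with the scaling too. More were also lower with the total signal (48 against 38) and under normexp (346 against 16), which keep the percentile scaling.

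More miRNAs were detected on liver NASH arrays, 354.5 against 288.8. Against brighter arrays that lift dim miRNAs above background as the whole cause, NASH arrays also had more miRNAs above a scaled level that lay over the detection limit of each array, by 16.7 as scaled, 21.3 over all probes and 13.2 under median centring (exact permutation p = 0.00926, 0.0185 and 0.00926). Array brightness differing with the diet may still account for much of the difference of 65.7 in detected miRNAs, and a biological effect of the diet stays open as untested. Diet and slide column cannot be told apart, since each column held arrays of 1 diet, and this holds for every pattern here.

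Chance allotment of arrays within weeks was examined by counting calls over 100 of the 108 splits of each tissue, and over 100 joint splits of both for the tissue difference. In liver 1 split, the real one, gave as many as 164, and the highest other gave 111; that split had 10 of 12 arrays under their own diet. In serum 1 split gave as many as 80, and the highest other gave 37, also with 10 of 12 arrays under their own diet. Among 29 other serum splits that part all 6 pairs of a slide row, as the real one does, the highest gave 8, and 37 came from a split that parts fewer. For the tissue difference 1 of 100 splits gave as many as 102, and the highest other gave 68. Of the splits drawn, only the real one gave as many calls for each of these 3 counts. The labels do not say whether the arrays of a group are separate mice or pools. Splits of arrays therefore cannot exclude chance differences between animals. They also say nothing of causes that follow the diet on the arrays, such as the slide column.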

How the results depend on the processing

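The test against a change of 0.5, the mean of weeks 1 and 2 without week 6, the fit without miRNAs at the floor on every array, the slide row block and the blocks for lists and for calls shared by the tissues were chosen after the data were seen. Of the alternative values of the named miRNAs, 1816 of 2006 in liver kept their direction and their side of the threshold, 135 lost and 29 gained a call and 26 turned sign; in serum these were 1582 of 1908, 211, 64 and 51. Totals not listed under an alternative stayed within 1.5 times of the value given in the report, while their splits of higher and lower could move further. The cause was not tested for any move listed below, except where the construction of the alternative is named. In counts of 0, the number in parentheses is that at an unadjusted p under 0.05 in limma. No usable value came from the tissue difference with no filter, because miRNAs at the floor on every array have no spread; in liver 1545 and in serum 1446 of 1881 were so. Among tested miRNAs 54 in liver and 51 in serum lay at the floor on every array, and 0 of them were called. Of the values of tested miRNAs 35.6% in liver and 39.1% in serum were at the floor, which limits what dim miRNAs can show.

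Scaled over all probes, the liver counts were 102 (64 higher, 38 lower) for the mean over weeks, 9 (9 higher, 0 lower) for week 1, 51 (25 higher, 26 lower) for week 2, 32 (28 higher, 4 lower) for week 6. The serum counts were 39 (32 higher, 7 lower) for the mean over weeks, 11 (7 higher, 4 lower) for week 1, 18 (17 higher, 1 lower) for week 2, 21 (19 higher, 2 lower) for week 6, 2 (0 higher, 2 lower) for control week 6 against week 1. The tissue difference gave 67 (40 higher, 27 lower). With the floor 4 times lower, the liver counts were 258 (143 higher, 115 lower) for the mean over weeks, 70 (50 higher, 20 lower) for week 1, 202 (129 higher, 73 lower) for week 2. In serum the counts were 140 (39 higher, 101 lower) for the mean over weeks, 11 (5 higher, 6 lower) for week 1, 36 (13 higher, 23 lower) for week 2, 113 (41 higher, 72 lower) for week 6. Tested against a change of 0.5 log2 units, the liver counts were 49 (27 higher, 22 lower) for the mean over weeks, 6 (3 higher, 3 lower) for week 1, 32 (18 higher, 14 lower) for week 2, 46 (25 higher, 21 lower) for week 6. Counts in serum were 23 (9 higher, 14 lower) for the mean over weeks, 0 (21 unadjusted) for week 1, 0 (34 unadjusted) for week 2, 3 (3 higher, 0 lower) for week 6. With the total signal per miRNA, the liver counts were 69 (27 higher, 42 lower) for week 1, 5 (3 higher, 2 lower) for control week 6 against week 1. The serum counts were 22 (6 higher, 16 lower) for control week 6 against week 1, 7 for the difference between weeks. Under normexp, whose offset takes the place of a floor before scaling, the liver counts were 7 (3 higher, 4 lower) for week 1, 50 (15 higher, 35 lower) for week 2, 67 (13 higher, 54 lower) for week 6, 0 (3 unadjusted) for control week 6 against week 1, 0 (18 unadjusted) for the difference between weeks. In serum the counts were 362 (16 higher, 346 lower) for the mean over weeks, 15 (5 higher, 10 lower) for week 1, 330 (10 higher, 320 lower) for week 2, 335 (18 higher, 317 lower) for week 6, 313 (301 higher, 12 lower) for control week 6 against week 1, 0 (54 unadjusted) for the difference between weeks. Without scaling, the liver counts were 14 (14 higher, 0 lower) for week 1, 66 (64 higher, 2 lower) for week 2, 41 (41 higher, 0 lower) for week 6, 3 for the difference between weeks. Counts in serum were 44 (37 higher, 7 lower) for the mean over weeks, 13 (7 higher, 6 lower) for week 1, 30 (29 higher, 1 lower) for week 6, 77 (0 higher, 77 lower) for control week 6 against week 1, 0 (44 unadjusted) for the difference between weeks. The tissue difference gave 64 (25 higher, 39 lower). With no filter on detection, where 1881 miRNAs shared the adjustment, the liver counts were 9 (2 higher, 7 lower) for week 1, 63 (33 higher, 30 lower) for week 2, 57 (31 higher, 26 lower) for week 6, 0 (21 unadjusted) for control week 6 against week 1, 1 for the difference between weeks. The serum counts were 35 (10 higher, 25 lower) for the mean over weeks, 0 (38 unadjusted) for week 1, 0 (70 unadjusted) for week 2, 3 (2 higher, 1 lower) for week 6, 2 (1 higher, 1 lower) for control week 6 against week 1, 1 for the difference between weeks. With the replicate block, without the serum array that has no number, the liver counts were 12 (4 higher, 8 lower) for week 1, 0 (31 unadjusted) for control week 6 against week 1, 1 for the difference between weeks. In serum the counts were 30 (11 higher, 19 lower) for the mean over weeks, 0 (47 unadjusted) for week 1, 0 (79 unadjusted) for week 2, 16 (7 higher, 9 lower) for week 6, 3 (2 higher, 1 lower) for control week 6 against week 1, 0 (44 unadjusted) for the difference between weeks. With slide row as a block on all arrays, liver had 12 (4 higher, 8 lower) for week 1, 0 (31 unadjusted) for control week 6 against week 1 and 1 for the difference between weeks, and serum had 0 (60 unadjusted) for week 1 and 0 (83 unadjusted) for week 2.

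Under quantile normalization, the liver counts were 179 (82 higher, 97 lower) for week 2, 1 (0 higher, 1 lower) for control week 6 against week 1, 4 for the difference between weeks. Counts in serum were 21 (14 higher, 7 lower) for week 2, 98 (55 higher, 43 lower) for week 6, 0 (94 unadjusted) for control week 6 against week 1, 0 (51 unadjusted) for the difference between weeks. Under median centring, the liver counts were 0 (21 unadjusted) for control week 6 against week 1, 8 for the difference between weeks. The serum counts were 4 (2 higher, 2 lower) for control week 6 against week 1, 5 for the difference between weeks. With the mean of all probes of a miRNA, the liver count was 0 (19 unadjusted) for control week 6 against week 1. Over miRNAs detected on all 12 arrays of the tissue, the liver counts were 0 (13 unadjusted) for control week 6 against week 1, 0 (44 unadjusted) for the difference between weeks. In serum the counts were 23 (4 higher, 19 lower) for week 2, 0 (30 unadjusted) for the difference between weeks. The tissue difference gave 59 (14 higher, 45 lower). Without miRNAs at the floor on every array, the liver counts were 1 (1 higher, 0 lower) for control week 6 against week 1, 5 for the difference between weeks. Counts in serum were 23 (7 higher, 16 lower) for week 2, 78 (24 higher, 54 lower) for week 6, 0 (31 unadjusted) for the difference between weeks. With the haemolysis index as a covariate, the serum counts were 39 (12 higher, 27 lower) for the mean over weeks, 4 (3 higher, 1 lower) for week 2, 0 (17 unadjusted) for week 6, 0 (13 unadjusted) for the difference between weeks. In the mean of weeks 1 and 2 without week 6, the serum count was 36 (12 higher, 24 lower). Fitted on the arrays of a week alone, with fewer arrays for the spread, liver counts were 14 (8 higher, 6 lower) at week 1, 76 (47 higher, 29 lower) at week 2, 19 (9 higher, 10 lower) at week 6 and serum counts were 0 (48 unadjusted) at week 1, 0 (47 unadjusted) at week 2, 1 (0 higher, 1 lower) at week 6.

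Splits of higher and lower that moved by over 10 percentage points while the total stayed within 1.5 times were as follows. Under normexp, they were 32 and 172 for liver mean. Without scaling, they were 117 and 9 for liver mean, 2 and 0 for liver control and 11 and 1 for serum week 2. Under quantile normalization, they were 22 and 29 for liver week 1, 53 and 45 for serum mean and 44 and 51 for tissue difference. Over miRNAs detected on all 12 arrays, they were 16 and 21 for liver week 1, 29 and 58 for liver week 6, 4 and 4 for serum week 1, 16 and 46 for serum week 6 and 6 and 3 for serum control. Under median centring, they were 46 and 75 for liver week 2, 44 and 21 for serum mean, 4 and 1 for serum week 1, 10 and 3 for serum week 2, 37 and 19 for serum week 6 and 59 and 40 for tissue difference. With the total signal, they were 71 and 55 for liver week 6, 38 and 48 for serum mean, 4 and 5 for serum week 1, 9 and 7 for serum week 2 and 3 and 2 for liver lists. With the floor 4 times lower, they were 87 and 71 for liver week 6, 3 and 0 for liver control and 2 and 9 for serum control. Scaled over all probes, they were 2 and 0 for liver control. With the mean of all probes, they were 5 and 10 for serum week 2. With slide row, they were 14 and 44 for serum week 6 and 4 and 2 for serum control. With single arrays left out, splits moved so for liver week 2 without control week 2 replicate 1 (47 and 55) and liver week 6 without NASH week 6 replicate 1 (55 and 42). Liver control had 0 and 2 without control week 1 replicate 1 or either control array of week 2, and 0 and 3 without control week 1 replicate 2. Serum week 1 had 0 and 4 without control week 1 replicate 2, 3 and 3 without NASH week 1 replicate 1, 1 and 4 without either NASH array of week 2 and 1 and 5 without either of week 6. Serum week 2 had 4 and 9 without either control array of week 6, and serum control 2 and 10 without control week 1 replicate 1.

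For the lists, camera with an estimated correlation left 0 calls in liver and 0 in serum, against 7 and 1; the hepatocyte-enriched list alone was under 0.05 unadjusted in each tissue (p = 0.0346 and 0.0217). fry, which asks whether a list moved on balance in a direction, called 6 serum lists (1 higher, 5 lower), and the total signal gave 3 (1 higher, 2 lower). With the replicate block 2 serum lists passed (1 higher, 1 lower), and with slide row 3 (1 higher, 2 lower). Same-numbered arrays share a slide row, and in liver at week 1 arrays went with the other number. The fall of serum counts with the replicate block is not that of pairing alone, since the block also left out an array: without that array and with no block the mean over weeks had 69 and week 6 had 37, and with slide row and all arrays they had 76 and 58. Beyond the counts listed for them, neither block moved a count by over 1.5 times.

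Of the sign turns, 16 of 26 in liver and 8 of 51 in serum were of miRNAs called before or after; the others passed neither way. Under normexp liver had miR-342-5p at -0.093, miR-574-3p at -0.28, miR-185-5p at -0.016, miR-222-3p at -0.11, miR-18a-5p at -0.026, miR-200c-3p at -0.052, miR-141-3p at -0.15, miR-429-3p at -0.14, miR-434-3p at -0.16 and miR-300-3p at -0.033, and serum had miR-132-3p at -0.14 and miR-382-5p at -0.56. Scaled over all probes liver had miR-574-3p at -0.030, and serum had miR-23a-3p at 0.35, miR-29c-5p at 0.056, miR-29b-3p at 0.53, miR-92a-3p at 0.35, let-7b-5p at 0.026, let-7i-5p at 0.18, let-7c-5p at 0.28, let-7d-5p at 0.35, miR-16-5p at 0.49, miR-223-3p at 0.32 and miR-24-3p at 0.54. Under quantile normalization liver had miR-21a-5p at 0.040, miR-29b-3p at 0.044, miR-29a-3p at 0.18, let-7f-5p at 0.065, let-7a-5p at 0.48 and miR-126a-3p at 0.032, and serum had miR-344i at 0.0036, miR-721 at 0.12, miR-29b-3p at 0.093 and miR-300-3p at 0.028. Without scaling liver had miR-29c-5p at 0.22, miR-29b-3p at 0.016, miR-29a-3p at 0.25, miR-20a-5p at 0.037, miR-103-3p at 0.14, let-7a-5p at 0.20, miR-98-5p at 0.058, miR-486a-5p at 0.19 and miR-151-5p at 0.39, and serum had miR-155-5p at 0.015, miR-451a at 0.013, miR-23a-3p at 0.46, miR-29b-3p at 0.64, miR-25-3p at 0.0014, miR-92a-3p at 0.46, let-7b-5p at 0.14, let-7i-5p at 0.29, let-7c-5p at 0.39, let-7d-5p at 0.46, miR-16-5p at 0.60, miR-223-3p at 0.43 and miR-24-3p at 0.65. With the total signal serum had miR-721 at 0.36, miR-29c-5p at 0.056 and miR-24-3p at 0.0065. Under median centring serum had miR-23a-3p at 0.19, miR-29b-3p at 0.37, miR-92a-3p at 0.19, let-7i-5p at 0.025, let-7c-5p at 0.12, let-7d-5p at 0.19, miR-300-3p at 0.045, miR-126a-5p at 0.023, miR-16-5p at 0.33, miR-223-3p at 0.17 and miR-24-3p at 0.38. With the floor 4 times lower serum had miR-721 at 0.73 and miR-382-5p at -0.088. With the haemolysis index as a covariate serum had let-7c-5p at 0.071, let-7d-5p at 0.17 and miR-16-5p at 0.087. With the replicate block, or without control week 6 replicate 1, serum miR-126a-5p was at 0.0069, and without control week 6 replicate 2 it was at -0.098.

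Leaving out each array in turn, with the lone array of a group assumed to vary like the others, moved the liver counts between 137 and 174 for the mean over weeks, 13 and 51 for week 1, 82 and 134 for week 2, 78 and 110 for week 6, 1 and 5 for control week 6 against week 1 and 6 and 37 for the difference between weeks. Serum counts lay between 49 and 118, 1 and 14, 0 and 53, 12 and 69, 4 and 30, and 1 and 32 in the same order. The tissue difference lay between 85 and 121, the correlation between 0.036 and 0.113, and the haemolysis index between -0.65 and -0.24. The liver count for week 1 became 13 without control week 1 replicate 1, 21 without control week 1 replicate 2, 18 without NASH week 1 replicate 1, 26 without NASH week 1 replicate 2. The liver count for control week 6 against week 1 became 1 without NASH week 1 replicate 1 or NASH week 1 replicate 2 or NASH week 2 replicate 1 or NASH week 2 replicate 2 or NASH week 6 replicate 1 or NASH week 6 replicate 2, 5 without control week 6 replicate 2. The liver count for the difference between weeks became 6 without control week 1 replicate 1 or NASH week 1 replicate 1, 8 without control week 1 replicate 2, 7 without NASH week 1 replicate 2 or NASH week 2 replicate 1, 31 without control week 2 replicate 1, 24 without NASH week 2 replicate 2, 37 without NASH week 6 replicate 1, 32 without NASH week 6 replicate 2. The serum count for the mean over weeks became 51 without NASH week 1 replicate 1 or NASH week 6 replicate 2, 49 without NASH week 2 replicate 1. The serum count for week 1 became 14 without control week 1 replicate 1, 2 without NASH week 1 replicate 2, 10 without control week 2 replicate 1 or control week 2 replicate 2, 1 without control week 6 replicate 1 or control week 6 replicate 2. The serum count for week 2 became 1 without control week 1 replicate 1 or control week 1 replicate 2, 5 without NASH week 1 replicate 1 or NASH week 1 replicate 2, 53 without control week 2 replicate 1, 26 without control week 2 replicate 2, 0 without NASH week 2 replicate 1 or NASH week 2 replicate 2. The serum count for week 6 became 29 without control week 1 replicate 1 or control week 1 replicate 2, 19 without control week 6 replicate 1, 12 without NASH week 6 replicate 2. The serum count for control week 6 against week 1 became 5 without control week 1 replicate 2 or NASH week 1 replicate 1 or NASH week 1 replicate 2 or NASH week 2 replicate 1 or NASH week 2 replicate 2, 17 without control week 2 replicate 1 or control week 2 replicate 2, 4 without control week 6 replicate 1 or NASH week 6 replicate 1 or NASH week 6 replicate 2, 30 without control week 6 replicate 2. The serum count for the difference between weeks became 7 without control week 1 replicate 1, 5 without NASH week 1 replicate 1, 32 without control week 2 replicate 1, 18 without control week 2 replicate 2, 1 without NASH week 2 replicate 1 or NASH week 2 replicate 2, 8 without control week 6 replicate 2, 10 without NASH week 6 replicate 1.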
